A study of Homo sapiens with 18 samples.

How the data were processed

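ATAC-seq libraries were made from Kelly and BE2C cells transduced with the empty lentiviral vector or with 1 of 2 hairpins against AHR. Per the labels' protocols, each library started from 50K cells, the transposase reaction ran for 30 min and the fragments were amplified in 10 PCR cycles. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Trimmomatic 0.33, BWA 0.7.17, MACS2 2.1.0 and deepTools 3.1.3, and the build was hg19. The role and settings of each tool, any removal of duplicate or mitochondrial reads and any shift of read ends for the transposase are not given in the sources used here. Such steps could move summits by a few bases and change which peaks pass the caller.

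The values used were 18 lists of peaks in the caller's 10-column layout, deposited by the authors as 1 list per library with no pooling across libraries. Each peak carried an integer score set by the authors' caller. Each peak also carried the fold enrichment over local background at its summit, the authors' own value, deposited as a linear ratio. The −log10 p-value and −log10 q-value of each peak were deposited by the authors as the caller gave them. The highest q-value in any list was 0.05, so the lists end where the caller's threshold fell. These values belong to single peaks and were used only to describe, rank or filter peaks within a list. Peak lists give no value where no peak was called, so absence means that no peak passed, not that the site was closed.

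Peaks on chromosomes 1 to 22 and X were kept, which left out between 0.197% and 0.83% of a list. Groups were taken from the genotype and cell line labels. The number and covered length of peaks were compared on the log2 scale with two-sided exact permutation tests in which labels were exchanged within a line (400 arrangements for both lines, 20 for 1 line), with Benjamini-Hochberg adjustment over 3 comparisons. For all other comparisons each list was shortened to its strongest peaks by −log10 p, 9204 in Kelly and 25660 in BE2C, the length of the shortest list of the line. Similarity was the Jaccard index of covered bases, tested over 280 groupings of the 9 libraries. Regions were made by merging the shortened lists of a line at an overlap of at least 1 bp, and a library had a region if any of its peaks overlapped it. Overlap between lines was set against label arrangements whose own lists gave at least 0.5 of the real expected overlap, a condition added after the data were seen. The overlap of hairpins was set against the product of the list lengths over the number of regions and against 100 simulations of unchanged groups with the same controls. Up to 5 gained and 5 lost regions per line were named, ordered by the lowest fold among the libraries with the peak, with regions found in both lines first; this rule and the main tests were fixed before the data were examined. Regions named for 1 hairpin, for the lines or for both lines follow the same order but were chosen after their values were seen.

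The fold and −log10 p of a peak together fix the pileup (the number of overlapping reads at the summit) and the local background, if the fold is the pileup over the background with a pseudocount of 1 on each and p is a Poisson tail. Solved this way for peaks with a fold of at least 1.5, at least 99.98% of the solved pileups of any library were whole numbers within 0.05. The share of peaks solved was 67.9% in replicate 1 of Kelly shAhR-1 and at least 98.8% in every other library. The lowest local background of a library was taken as its genome-wide background. The highest solved pileup on the mitochondrial chromosome divided by this background stood for the mitochondrial content. Local background was summarised in bins of 100 kb with values in at least 7 of the 9 libraries of a line, and a high bin had at least 20 times the genome-wide background. Read depth was not used here in any other form, so the background served as its measure, and the shortest list limited every comparison of regions.

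The comparison between the lines, the shares by chromosome and by window of 10 Mb, the solved pileups and the positions of changed regions were added after the data were seen. Windows with a mean share of at least 0.1% were tested, and runs of at least 3 neighbouring windows past the threshold with a log2 ratio of at least 0.5 were joined.

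The functions were tested on simulated data. With 100 gained and 100 lost regions among 16752 regions of Kelly, each missed by a library with a probability of 5%, the comparison of both hairpins recovered 73% of the gained and 86% of the lost regions. With the same numbers among 41422 regions of BE2C it recovered 66% and 80%. Among the other, unchanged regions it called 12 gained and 18 lost in Kelly and 22 and 30 in BE2C. The permutation test over both lines called 5.2% of 1000 unchanged comparisons. The test between lines recovered 56% of 200 changed regions among 17000 and called 0 unchanged ones. Of 4427 simulated peaks 99.98% could be solved, and the pileup was recovered in 100% of those solved. The simulated backgrounds lay mostly above the genome-wide backgrounds of the real libraries, so recovery at low background was little tested.

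Alternatives covered stricter thresholds, merged peaks, covered bases, full lists, 20000 strongest peaks, ranking by fold, summit windows, other overlap rules, presence in at least 2 of 3 libraries, a replicate block and each library left out. Lists of 9204 peaks in both lines and the overlap between lines without replicate 1 of Kelly shAhR-1 were added after the data were seen, as was the similarity of shAhR-1 with single libraries left out. The location of peaks relative to genes, the number of peaks linked to genes, gene lists and motif content were planned but not run, since an hg19 annotation and sequence were not used here. Replicates were not duplicates, with at most 0.174% of peaks identical between 2 libraries of a group. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.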

Results

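Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in Kelly and BE2C, established human neuroblastoma cell lines. Per the series title, the study concerns AhR and dedifferentiation in neuroblastoma with MYCN amplification. AhR, encoded by AHR, is a ligand-activated transcription factor of the bHLH-PAS family. Cells of each line received a lentivirus with the empty vector pLKO or with 1 of 2 short hairpin RNAs against AHR, named here shAhR-1 and shAhR-2. Each of the 6 groups held 3 libraries, 18 in all. The values used here were 1 list of called peaks per library, on hg19 coordinates, and the level of AHR itself was not analysed here. On chromosomes 1 to 22 and X the lists held between 9204 and 81637 peaks. Read totals were not used here. The genome-wide background solved from the peak values, which moves with sequencing depth, lay between 0.601 and 4.42 overlapping reads per position. The labels speak of triplicates of collected cells and do not say that these were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

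Peak lists were longer with shAhR-2 than with the empty vector in both lines. In Kelly the mean list held 63668 ± 2820 peaks with shAhR-2 and 28295 ± 7586 with pLKO (SD, n = 3 each). In BE2C it held 78347 ± 2989 peaks with shAhR-2 and 38422 ± 5289 with pLKO (SD, n = 3 each). Every shAhR-2 list was longer than every pLKO and shAhR-1 list of its line. Covered sequence was 38.2 ± 1.69 Mb against 16.8 ± 5.89 Mb in Kelly and 52.4 ± 3.00 Mb against 22.9 ± 5.30 Mb in BE2C (SD, n = 3 each). With shAhR-1 the mean lists held 19145 ± 8614 peaks in Kelly and 32608 ± 10777 in BE2C (SD, n = 3 each).

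The geometric mean ratio of peak numbers over both lines was 2.18 for shAhR-2 against pLKO, with p = 0.005 in a two-sided exact permutation test within lines (adjusted p = 0.0075 over 3 comparisons). It was 3.01 for shAhR-2 against shAhR-1, also with p = 0.005 in the exact test (adjusted p = 0.0075). For shAhR-1 against pLKO it was 0.724 and did not pass the test (exact p = 0.115, adjusted p = 0.115). The smallest p that 400 label arrangements allow is 0.005, and within 1 line the smallest is 0.1. Without replicate 1 of BE2C shAhR-1, the ratio of shAhR-1 to pLKO on the log2 scale moved from −0.47 to −0.59 and passed the threshold (exact permutation test, adjusted p = 0.035). An exact permutation test of the difference between the lines gave p = 0.865 for shAhR-2 against pLKO and 0.625 for shAhR-1 against pLKO. Its arrangements also undo an effect that both lines share. It could therefore hardly detect a difference in size between effects of the same direction. The ratios in Kelly and BE2C were 2.31 and 2.05 for shAhR-2 against pLKO, and 0.635 and 0.826 for shAhR-1 against pLKO.

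Background and mitochondrial signal moved with the same libraries. The genome-wide background was 2.78 ± 0.196 overlapping reads with shAhR-2 and 1.65 ± 0.347 with pLKO in Kelly (SD, n = 3 each). In BE2C it was 3.79 ± 0.556 with shAhR-2 and 1.62 ± 0.204 with pLKO (SD, n = 3 each). The highest pileup on the mitochondrial chromosome, divided by that background, was 7314 ± 1415 with shAhR-2 and 21303 ± 6236 with pLKO in Kelly (SD, n = 3 each). In BE2C it was 5514 ± 577 against 16685 ± 766 (SD, n = 3 each). Both differences passed the exact permutation test over both lines (p = 0.005 each, adjusted p = 0.0167 over 10 tests). With shAhR-1, the test gave exact p = 0.19 for the background and 0.985 for the mitochondrial ratio. The median fold of peaks over local background, the authors' own value per peak, was 4.83 ± 0.123 with shAhR-2 and 6.22 ± 0.865 with pLKO in Kelly, and 4.83 ± 0.401 against 6.07 ± 0.309 in BE2C (SD, n = 3 each).

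**Figure D1:**
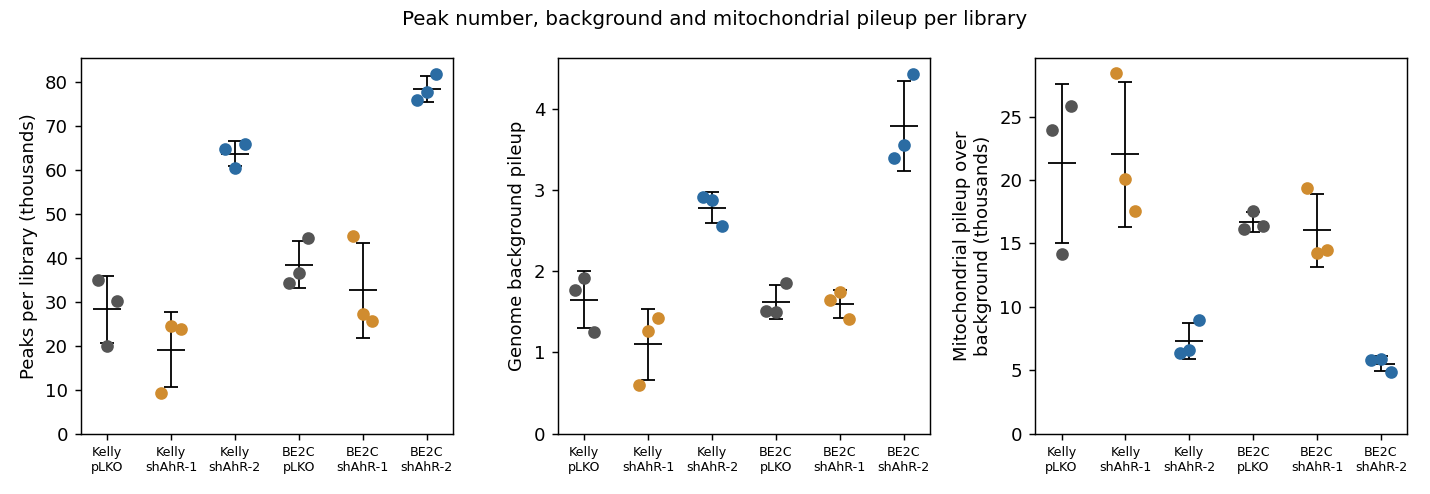
Peak number on chromosomes 1 to 22 and X in units of 1000 peaks, genome-wide background pileup in overlapping reads, and highest mitochondrial pileup over that background in units of 1000. Points are the 18 libraries, and horizontal lines with bars give the mean ± SD of the 3 libraries of a group. The shAhR-2 libraries had more peaks, a higher background and a lower mitochondrial ratio than the pLKO libraries in both lines.

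Because a longer list overlaps more of any other list, the lists were compared at equal length, 9204 peaks per library in Kelly and 25660 in BE2C, the strongest by −log10 p. Averaged over all groups, libraries of the same group shared more sequence than libraries of different groups in both lines. In Kelly the mean Jaccard index (bases shared over bases covered by either list) was 0.574 within groups and 0.454 between groups. In BE2C the means were 0.648 and 0.531. The shAhR-2 libraries resembled each other most, with a mean index of 0.701 in Kelly and 0.742 in BE2C, while the shAhR-1 libraries had 0.419 and 0.555. Between pLKO and shAhR-1 the mean index was 0.458 in Kelly and 0.572 in BE2C, above the values within shAhR-1, but 1 library in each line decided this order. Without shAhR-1 replicate 1 in Kelly the values were 0.591 within shAhR-1 and 0.543 with pLKO, and without shAhR-1 replicate 3 in BE2C they were 0.613 and 0.598. Between pLKO and shAhR-2 it was 0.533 and 0.525. Replicate 1 of Kelly shAhR-1, which set the list length in that line, had between 0.213 and 0.336 with the other Kelly libraries. Between the lines, lists of 9204 peaks had a mean index of 0.429, against 0.484 within Kelly and 0.563 within BE2C.

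The difference of within-group and between-group means was 0.120 in Kelly and 0.117 in BE2C. In each line the exact permutation test (two-sided, n = 9 libraries) gave p = 0.00357 (adjusted p = 0.00357 over the 2 lines), the smallest that 280 groupings allow.

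**Figure D2:**
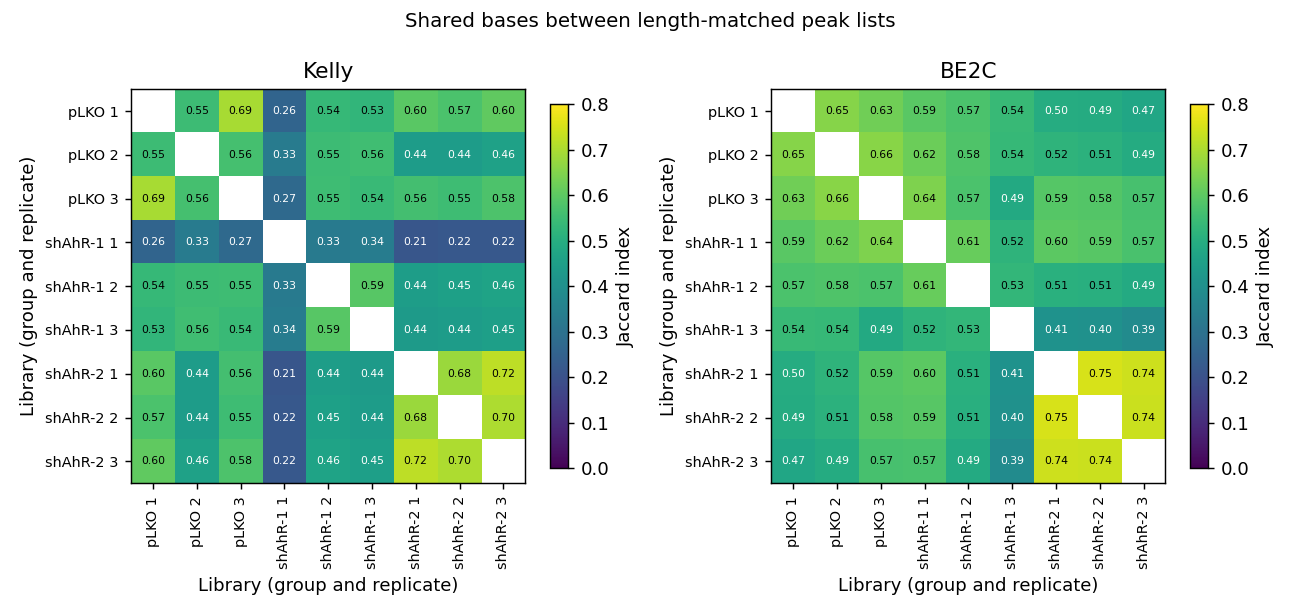
Jaccard index of shared bases for each pair of length-matched lists in Kelly (9204 peaks per library) and BE2C (25660 peaks per library), on a colour scale from 0 to 0.8. The shAhR-2 libraries form the block of highest values in each line, and replicate 1 of Kelly shAhR-1 has the lowest values.

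The comparison of both hairpins with the empty vector asked which regions changed whenever AHR was targeted. A region counted as gained when all 6 hairpin libraries of a line had a length-matched peak there and none of the 3 pLKO libraries did, and as lost in the reverse case. In Kelly 39 regions were gained and 87 were lost, among 16752 regions of which 3987 had a peak in all 9 libraries. In BE2C 193 were gained and 413 were lost, among 41422 regions of which 15100 had a peak in all 9 libraries. A gain needed a peak in 6 libraries and a loss in only 3, so the rule itself favours losses. With labels shuffled independently in each region, 11.8 gained and 15.6 lost regions were expected in Kelly and 24.4 and 37.0 in BE2C. Both counts exceeded these expectations, the lost ones by a larger factor, so the rule alone does not give the excess of lost regions. The shuffling does not keep libraries of a group alike, and the counts depended on the rule for presence. The excess can therefore still not be read as a net closing. The regions lost in both lines lay on chromosome 3 at 43218181 to 43218660 in Kelly and 43218191 to 43218753 in BE2C, on chromosome 1 at 48269714 to 48270261 and 48269709 to 48270189, and on chromosome 1 at 160332010 to 160333100 and 160331983 to 160333006. No gained region was shared between the lines at matched length (0 regions), but without replicate 1 of Kelly shAhR-1, 5 gained and 6 lost regions were shared.

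Ordered by the lowest fold among the libraries with the peak, the lost regions of Kelly went on with chromosome X at 10711788 to 10712597, where the 3 pLKO libraries had folds of at least 9.94, and chromosome X at 3799486 to 3800674, at least 8.84. In BE2C the next lost regions lay on chromosome 2 at 68107236 to 68107983, with folds of at least 9.95, and chromosome 1 at 155953149 to 155953931, at least 9.47. The gained regions of Kelly were led by chromosome 14 at 27289364 to 27289997, where the 6 hairpin libraries had folds between 7.84 and 13.6. They were followed by chromosome 1 at 216629760 to 216631023, chromosome 15 at 33452422 to 33453745, chromosome X at 123813104 to 123814499 and chromosome 5 at 123462944 to 123464282. The gained regions of BE2C were led by chromosome X at 135686592 to 135687680, with folds between 7.72 and 9.37 and no peak in the full lists of the pLKO libraries. They were followed by chromosome 3 at 85224615 to 85226086, chromosome 7 at 85139044 to 85140512, chromosome 6 at 105048137 to 105049430 and chromosome X at 21733338 to 21734501. Genes and gene features at these positions were not analysed here.

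Some of the libraries that lacked a region had a weaker peak there in their full list. In Kelly, each of the 39 gained and 87 lost regions had such a peak in at least 1 lacking library, and in BE2C all but 20 of the 193 gained and 29 of the 413 lost regions did. The number of lacking libraries with one varied among the named regions, from 0 of 6 at the lost region of BE2C on chromosome 1 at 160331983 to 160333006, and 2 of 6 at the lost region of Kelly on chromosome 3, to 3 of 3 at the gained region of Kelly on chromosome 15. Of the gained and lost regions of BE2C, 86.0% and 57.9% had a peak in at least 1 full list of Kelly, and of those of Kelly 97.4% and 95.4% had one in the full lists of BE2C, which were longer on average in each condition.

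A single region seen in 6 libraries against 3 cannot pass a correction over all regions, so the counts were set against the 84 choices of 3 libraries as the control trio. In Kelly 3 of the 84 choices gave at least 126 changed regions, and in BE2C 2 of 84 gave at least 606. Choosing the shAhR-2 trio gave more than the pLKO trio in each line, with 420 regions in Kelly and 917 in BE2C. Leaving out replicate 1 of Kelly shAhR-1, whose short list set the number of peaks compared, raised the Kelly count to 480, and leaving out replicate 2 of Kelly pLKO raised it to 242. The counts depended on the rule for presence. When a peak had to cover at least 50% of the region, Kelly had 3 gained and 87 lost regions and BE2C had 75 gained and 337 lost, and full lists at −log10 q of at least 5 gave 13 gained and 85 lost in Kelly and 65 gained and 91 lost in BE2C. In BE2C, leaving out pLKO replicate 1, 2 or 3 gave 951, 931 and 942.

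**Figure D3:**
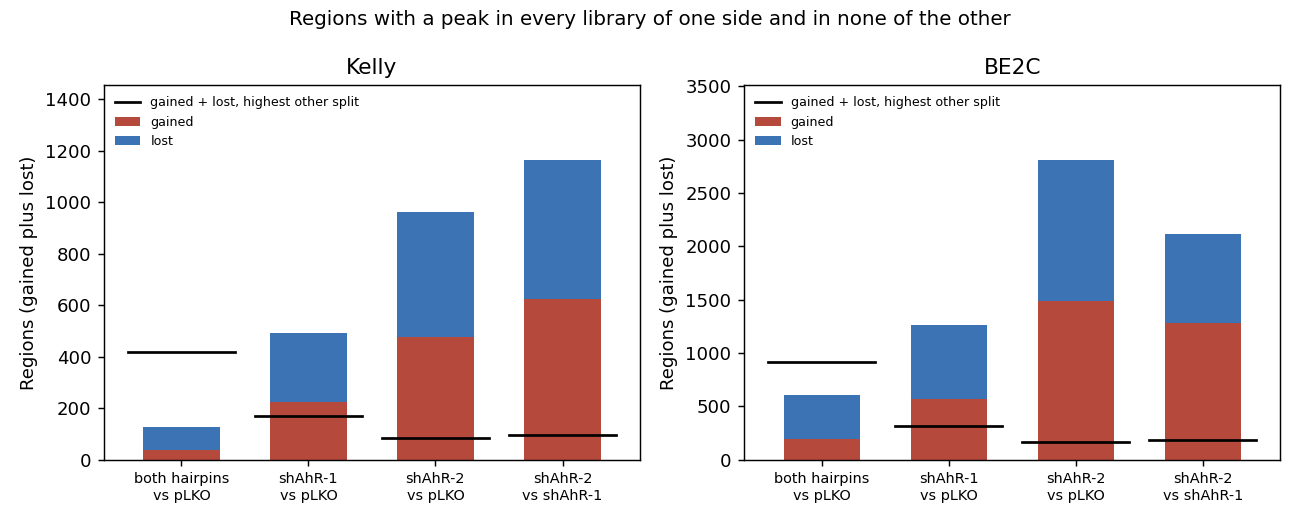
Number of regions gained (red) and lost (blue), stacked, for each comparison in Kelly and BE2C at matched list length. Black lines mark the highest total of gained plus lost regions among the other splits of the same libraries, which lies above the bar for both hairpins against pLKO and below it in the comparisons of 3 against 3 libraries.

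Taken 1 hairpin at a time, shAhR-2 was set apart from the empty vector at more regions than shAhR-1. The rule needs agreement within each group, and the shAhR-2 libraries resembled each other most. The counts therefore do not measure distance from the empty vector alone. With a peak in at least 2 of 3 libraries, the totals for shAhR-1 and shAhR-2 were 1510 and 2030 in Kelly and 3747 and 5637 in BE2C. With shAhR-1, a peak was present in all 3 hairpin libraries and no pLKO library at 223 regions in Kelly and 565 in BE2C, and the reverse held at 270 and 695. With shAhR-2, 476 regions were gained and 485 lost in Kelly, and 1489 were gained and 1320 lost in BE2C. Between the hairpins, 624 regions in Kelly and 1280 in BE2C had a peak in every shAhR-2 library and no shAhR-1 library, and 540 and 835 had the reverse.

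With 3 libraries against 3 there are 10 splits, too few for a p under 0.05, and no p is given per region. The highest total of any other split was 168 against 493 for shAhR-1 in Kelly, 83 against 961 for shAhR-2 in Kelly, 316 against 1260 for shAhR-1 in BE2C and 168 against 2809 for shAhR-2 in BE2C. The balance of gained and lost regions depended on the list length and on the rule for presence. At matched length the stricter coverage rule given above was also applied. With shAhR-2 it gave 649 gained and 350 lost regions in Kelly and 3722 gained and 798 lost in BE2C. With shAhR-1 it gave 77 gained and 486 lost in Kelly and 244 gained and 606 lost in BE2C. With the lists at full length, shAhR-2 had 12181 gained and 219 lost regions in Kelly and 15180 gained and 180 lost in BE2C, while shAhR-1 had 77 gained and 915 lost in Kelly and 165 gained and 877 lost in BE2C. Between the hairpins the full lists gave 18006 gained and 57 lost in Kelly and 16677 gained and 21 lost in BE2C, and for both hairpins in BE2C they gave 136 gained and 131 lost. Single libraries moved several of these totals by over 1.5 times. Leaving out replicate 1 of Kelly shAhR-1 gave 1812 regions for shAhR-1 against pLKO and 3937 for shAhR-2 against shAhR-1. For Kelly shAhR-1 against pLKO, leaving out pLKO replicate 2 gave 907, shAhR-1 replicate 2 gave 867 and shAhR-1 replicate 3 gave 903. For BE2C shAhR-1 against pLKO, leaving out pLKO replicate 1 gave 1920, shAhR-1 replicate 1 gave 2310 and shAhR-1 replicate 3 gave 2162. Leaving out BE2C shAhR-1 replicate 1 gave 3698 for shAhR-2 against shAhR-1.

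At matched list length some regions were gained or lost with both hairpins. In Kelly, 39 of the 223 regions gained with shAhR-1 were also gained with shAhR-2, and 87 of the 270 lost regions were lost with both. In BE2C the shared numbers were 193 of 565 gained and 413 of 695 lost regions. Both comparisons used the same 3 pLKO libraries, which alone makes lists overlap. With unchanged groups set against the same controls in 100 simulations, the mean overlap was 11.9 gained and 15.4 lost regions in Kelly and 24.5 and 36.6 in BE2C. Independent lists of these lengths would share 6.34 gained and 7.82 lost regions in Kelly and 20.3 and 22.1 in BE2C. The 3 control libraries cannot be divided into parts of at least 2, so part of the excess may come from the shared controls. At full list length the overlap in Kelly, 41 gained and 96 lost, lay below the simulated means of 42.7 and 165, and in BE2C it was 136 gained against 59.8 and 131 lost against 166.

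The lines have no library in common, so a region changed the same way in both does not rest on shared controls. The shAhR-2 libraries of both lines did share longer lists, a higher background and a lower mitochondrial ratio, and the labels give no batch. Among 14820 regions seen in both lines, shAhR-2 changed 29 the same way, 17 gained and 12 lost, and 5 in opposite ways. With shAhR-1, 11 regions changed the same way, 8 gained and 3 lost, and 1 in opposite ways. The 3 regions lost with both hairpins in both lines, named above, belong to each of these sets. Regions gained with shAhR-2 in both lines were led by chromosome 1 at 102718000 to 102719342, with folds between 9.22 and 10.5 in the 6 shAhR-2 libraries, and chromosome 13 at 70138914 to 70139961, between 8.66 and 11.2. Regions gained with shAhR-1 in both lines were led by chromosome 7 at 85139044 to 85140512, with folds between 7.44 and 14.7.

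Independent lists of the real lengths would share 10.3 regions the same way and 10.4 in opposite ways with shAhR-2, and 2.17 and 2.34 with shAhR-1. Of 200 label arrangements, the real one included, only 2 for shAhR-2 and 3 for shAhR-1 had lists long enough to give at least 0.5 of the real expected overlap, too few for a test. For both hairpins together, 68 of 7056 arrangements had such lists, and 3 of them gave at least 3 regions, the highest with 7. Without replicate 1 of Kelly shAhR-1 the counts were 190 for shAhR-2, 65 for shAhR-1 and 11 for both hairpins. For both hairpins, 2 of the 24 arrangements with such lists then reached 11, the highest with 46. With full lists, 2668 regions were shared for shAhR-2, 2664 gained and 4 lost, where independent lists would share 1435. For shAhR-1, 0 gained and 14 lost regions were shared, where independent lists would share 7.04 and another arrangement reached 46. For both hairpins the number was 0.

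The lines themselves were compared with lists of equal length. With lists of 9204 peaks for all 18 libraries, 83 regions had a peak in all 9 Kelly libraries and no BE2C library, and 169 had the reverse. The Kelly regions were led by chromosome 12 at 132166347 to 132167282, with folds between 8.59 and 16.6, and chromosome 7 at 116363786 to 116364920, between 7.91 and 15.0. The BE2C regions were led by chromosome X at 2171021 to 2171766, with folds between 10.8 and 16.5, and chromosome 14 at 46532778 to 46533781, between 10.2 and 17.6. Of the 83 Kelly regions, 11 had no peak in any full BE2C list, and of the 169 BE2C regions, 21 had none in any full Kelly list.

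An exact permutation test per region, two-sided and within conditions, was applied to the 16929 regions not seen in all 18 libraries. With Benjamini-Hochberg adjustment, 191 regions had a peak more often in Kelly and 376 more often in BE2C. The smallest p that 8000 arrangements allow is 0.00025. The comparison was added after the data were seen.

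The strongest peaks were spread differently over the chromosomes in the 2 lines. Chromosome 22 held 1.59 ± 0.252% of the 9204 peaks in Kelly and 0.622 ± 0.349% in BE2C, and chromosome 17 held 4.19 ± 0.374% and 2.38 ± 0.344% (SD, n = 9 each). Chromosome 20 held 1.83 ± 0.203% in Kelly and 2.91 ± 0.0782% in BE2C, and chromosome 9 held 3.60 ± 0.205% and 4.77 ± 0.238% (SD, n = 9 each). The shares in BE2C depended on condition and list length. For chromosome 22 they were 0.80% with pLKO, 0.891% with shAhR-1 and 0.174% with shAhR-2 at 9204 peaks, and 1.46%, 1.41% and 1.00% at 25660 peaks. For chromosome 17 in BE2C they were 2.37%, 2.73% and 2.04% at 9204 peaks and 3.71%, 3.64% and 3.38% at 25660. With full lists the pLKO libraries held 2.02% in Kelly and 1.48% in BE2C on chromosome 22, and 4.64% and 3.57% on chromosome 17, smaller ratios than at 9204 peaks. Long stretches differed in 1 direction. Windows of 10 Mb from 0 to 70 Mb of chromosome 1 held a 1.93-fold larger share in Kelly, those from 40 to 90 Mb of chromosome 17 a 1.96-fold larger share and those from 10 to 50 Mb of chromosome 22 a 2.62-fold larger share. In BE2C the share was 2.58-fold larger from 70 to 120 Mb of chromosome 9, 1.94-fold larger from 30 to 60 Mb of chromosome 20 and 1.67-fold larger from 200 to 250 Mb of chromosome 2.

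Of 286 windows tested, 180 passed the threshold, 85 higher in Kelly and 95 higher in BE2C (two-sided exact permutation tests, lowest adjusted p = 0.000803). The 4 chromosomes named above had adjusted p = 0.000523 over 23 exact permutation tests. These tests were also added after the data were seen, and windows were not compared at other list lengths. The number of DNA copies in each line was not analysed here. Neither these windows nor the regions that differ between the lines can therefore be read as accessibility alone.

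**Figure D4:**
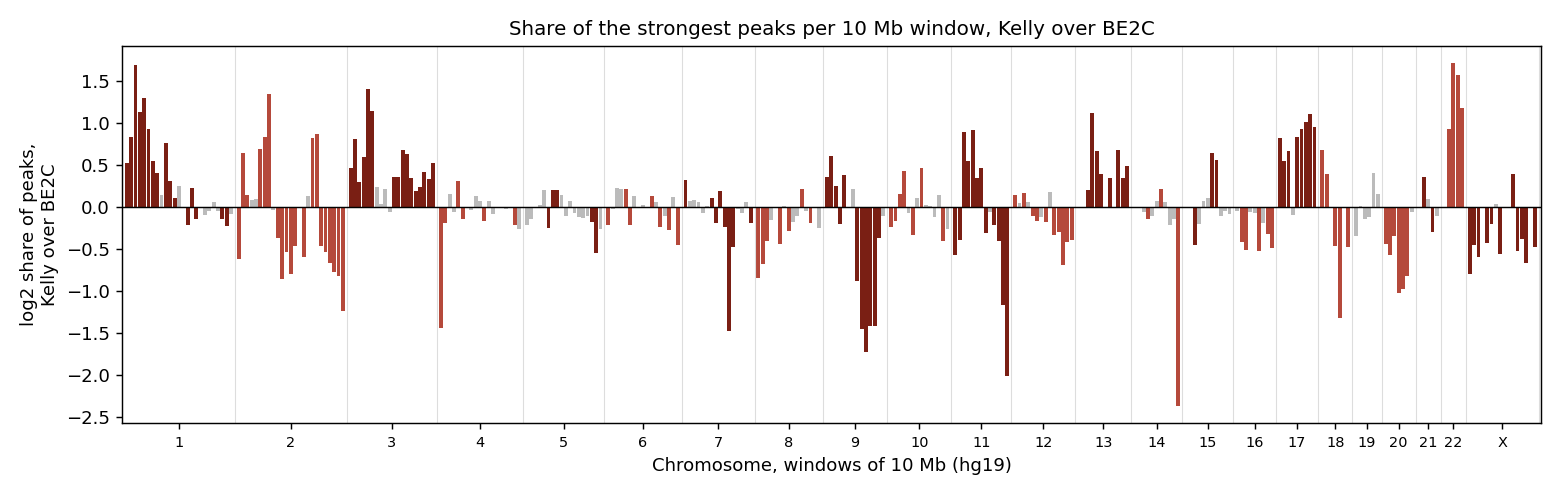
Log2 ratio of the mean share of the 9204 strongest peaks in Kelly over BE2C (9 libraries each) in windows of 10 Mb along chromosomes 1 to 22 and X. Red bars passed the exact test with Benjamini-Hochberg adjustment, in shades that alternate between chromosomes, and grey bars did not; 180 of 286 windows passed.

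Both lines had a block of very high local background on the short arm of chromosome 2, the arm that carries MYCN, the gene named as amplified in the series title. In Kelly it spanned 15800001 to 16900000, where the 11 bins of 100 kb had median local backgrounds between 81.4 and 151 times the genome-wide background. In BE2C it spanned 16000001 to 16700000, with the medians of 7 bins between 25.0 and 104 times. Its outer bins varied between the BE2C libraries, from 2.37 to 335 times at 16000001 to 16100000 and from 1.92 to 54.7 times at 16600001 to 16700000. The limits of the block in BE2C were therefore not shared by every library. The median bin of the genome lay at 1.77 times in Kelly and 1.68 times in BE2C. The next longest run of bins above 20 times held 2 bins in each line, on chromosome 4. The gene content of the block was not looked up on hg19. These values came from the local background solved for each peak and describe 9 libraries per line, with no test.

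**Figure D5:**
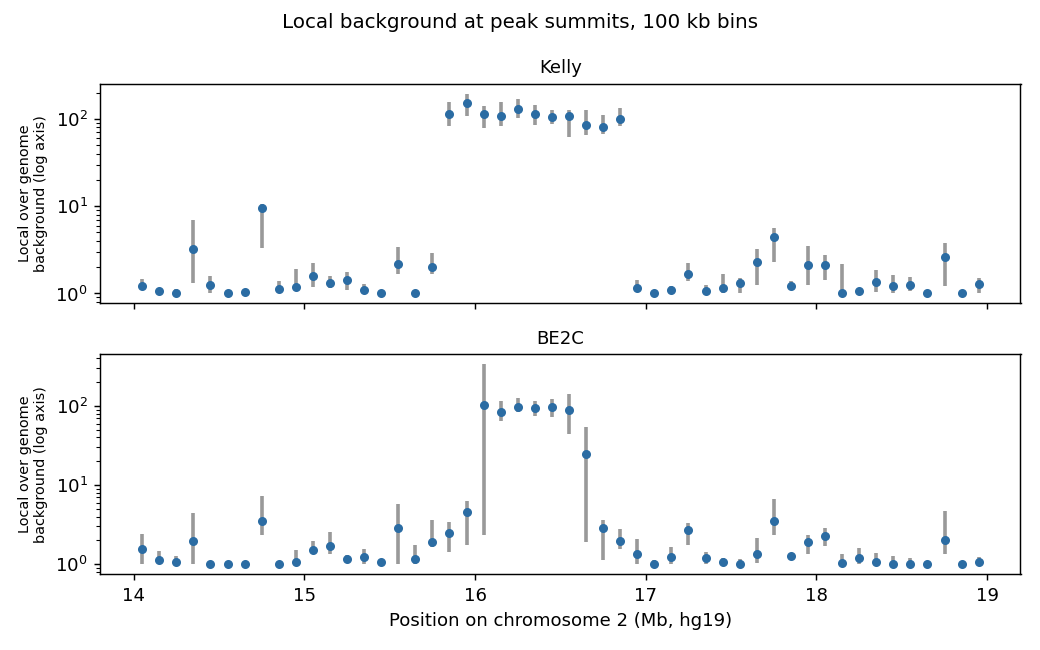
Local background at peak summits over the genome-wide background, on a log axis, in bins of 100 kb along chromosome 2 of hg19. Points are medians and bars the lowest and highest of the 9 libraries of a line. By the medians, the raised block spans 15800001 to 16900000 in Kelly and 16000001 to 16700000 in BE2C.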

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

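The test of chromosome shares was chosen after the data were seen. It compared the share of length-matched peaks on each chromosome between each hairpin and pLKO, and 4 of its 46 comparisons are listed because every shAhR-2 library moved one way from every pLKO library in Kelly and the opposite way in BE2C, which chance gives for a share of 0.005 of comparisons. The exact permutation test of the difference between the lines, two-sided, gave p = 0.005 for each, the smallest possible. That p follows from the rule by which the 4 were chosen, so it adds no support. The adjusted p was 0.0575, so none passed after correction (0 of 46, with 9 at an unadjusted p under 0.05).

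On chromosome 19 the effect of shAhR-2 in Kelly minus that in BE2C was 0.65 on the log2 scale, with shares of 4.48 ± 0.333% against 3.44 ± 0.268% for pLKO in Kelly and 3.50 ± 0.157% against 4.21 ± 0.0958% in BE2C (SD, n = 3 each). On chromosome 1 the difference was 0.15, from log2 effects of 0.06 in Kelly and −0.09 in BE2C. On chromosome 9 the difference was −0.28, from −0.17 in Kelly and 0.10 in BE2C. On chromosome 15 the difference was 0.18, from 0.15 in Kelly and −0.03 in BE2C. With full lists the differences were −0.02 on chromosome 19, where the effects were −0.52 in Kelly and −0.50 in BE2C, −0.01 on chromosome 15, 0.09 on chromosome 1 and −0.30 on chromosome 9, with exact permutation p = 0.97, 0.915, 0.03 and 0.005.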

How the results depend on the processing

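The tests with lists of 9204 peaks in both lines, the similarity of shAhR-1 without single libraries, the overlap between lines without 1 library and the comparison between the lines were chosen after the data were seen. With a library left out, 93 of the recomputed values kept their side of the threshold or stayed within 1.5 times, 17 counts moved further and 1 value newly passed; under the other alternatives 53 held and 49 counts moved. No ratio of peak numbers and no similarity difference changed sign under these alternatives. The log2 ratio of peak numbers ranged with single libraries left out from 1.01 to 1.21 for shAhR-2 against pLKO, from 1.36 to 1.72 for shAhR-2 against shAhR-1 and from −0.59 to −0.23 for shAhR-1 against pLKO. The lowest of these, without BE2C shAhR-1 replicate 1, passed the threshold; its cause was not tested. Requiring a fold of at least 5 lowered the ratio for shAhR-2 against pLKO to 0.66, still past the threshold. Similarity differences ranged from 0.0822 to 0.165 in Kelly and from 0.0812 to 0.160 in BE2C.

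Counts of regions depended on list length. Values are given in the order both hairpins, shAhR-1, shAhR-2 and shAhR-2 against shAhR-1. Full lists gave 992, 12400 and 18063 for the last 3 of these in Kelly, and 267 for both hairpins, 15360 for shAhR-2 and 16698 between hairpins in BE2C. Full lists at −log10 q of at least 5 gave 848, 9218 and 15351 for the last 3 in Kelly and 156, 706, 13871 and 15094 in BE2C. The 20000 strongest peaks, which leave out Kelly shAhR-1 replicate 1 and pLKO replicate 2, gave 943, 3011, 3606 and 3946 in Kelly. Lists of 9204 peaks gave 187, 397, 1507 and 1088 in BE2C. Ranking by fold gave 1562 for shAhR-2 and 2106 between hairpins in Kelly and 4330 and 3978 in BE2C. A peak covering at least 50% of the region gave 2047 between hairpins in Kelly, 4520 for shAhR-2 in BE2C and 4133 between hairpins there. It kept other totals within 1.5 times but lowered the gained regions of both hairpins to 3 in Kelly and 75 in BE2C, and those of shAhR-1 to 77 and 244. It raised the gained regions of shAhR-2 to 649 in Kelly and 3722 in BE2C, and those between hairpins to 1822 and 3811. The lost regions fell to 350 and 798 for shAhR-2 and to 225 and 322 between hairpins. Absence from the full lists as well left 0, 11, 17 and 45 in Kelly and 49, 298, 412 and 453 in BE2C. A peak in at least 2 of 3 libraries gave 437, 1510, 2030 and 2622 in Kelly and 1805, 3747, 5637 and 4889 in BE2C. The last 2 rules change counts by their own construction; for ranking and coverage the cause was not tested. Summit windows moved no count by over 1.5 times.

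With single libraries left out, which relaxes the rule, counts ranged in Kelly from 133 to 480 for both hairpins, 633 to 1812 for shAhR-1, 1178 to 1354 for shAhR-2 and 1384 to 3937 between hairpins. In BE2C they ranged from 643 to 951, 1774 to 2310, 3407 to 3971 and 2594 to 3698. Regions changed the same way in both lines numbered 0 for both hairpins and 2668 for shAhR-2 with full lists, and 26 for shAhR-1 and 109 for shAhR-2 with 9204 peaks. Without Kelly shAhR-1 replicate 1 they numbered 11, 65 and 190. Regions that differ between the lines numbered 2058 with 20000 peaks. At matched length the shortest list, 9204 peaks in Kelly and 25660 in BE2C, limits these counts; how far depth sets its length was not tested. Location relative to genes, linked genes, gene lists and motif content, with their alternatives, were not run.

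With the replicate number as a block, the log2 ratio for shAhR-2 against pLKO was 1.12 with exact p = 0.0313, the smallest possible, and adjusted p = 0.0469. It was 1.59 for shAhR-2 against shAhR-1 and −0.47 for shAhR-1 against pLKO, so the replicate block changed no call. Same-numbered libraries did not deviate together: 0 of 18 pairs had a correlation over 0.1, the values lay between −0.0567 and 0.0296, and the best partner had the same number for 5 of 18.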

Other observations

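The tests chosen only after the results were seen were those of neighbouring regions, chromosome 19 positions, mitochondrial signal and the chromosome 2 block. The counts of other splits within a line were planned. The bounds used to read them, the arrangements over both lines and the splits that mix the lines were added after the results were seen. The thinning test and the test on the longest shAhR-1 list were written before their results, the thinning test after peak numbers and a count of peaks with a fold of at least 5 had been seen.

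Changed regions lay close to each other more often than random regions in some comparisons. Of the regions lost with shAhR-2 in BE2C, 21.6% had another such region within 50 kb, against a median of 8.18% in 1000 random draws. For regions gained with shAhR-2 in Kelly the shares were 9.45% and 3.57%. These comparisons each had p = 0.000999 in the one-sided permutation test, the smallest that the draws allow (adjusted p = 0.00266 over 16 tests). For shAhR-2 against pLKO the opposite directions did not pass after correction. Lost regions in Kelly had 5.36% against 3.71% (permutation p = 0.112, adjusted p = 0.163). Gained regions in BE2C had 11.3% against 9.20% (permutation p = 0.029, adjusted p = 0.0533). Regions lost with both hairpins in BE2C, with 5.33% against 2.42%, did not pass after correction (permutation p = 0.03, adjusted p = 0.0533). For shAhR-2 against shAhR-1 in Kelly, gained regions had 10.3% against 4.65% and lost regions 10.0% against 4.07%. In BE2C, lost regions had 10.9% against 5.27% for shAhR-2 against shAhR-1. Regions lost with shAhR-1 against pLKO in BE2C had 9.64% against 4.604%. Each of these also had permutation p = 0.000999 (adjusted p = 0.00266). No other comparison passed after correction.

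On chromosome 19, gained and lost regions of shAhR-2 lay in different parts. In the windows from 30 to 40 Mb and 50 to 60 Mb lay 37 of 56 gained and 1 of 18 lost regions in Kelly, and 15 of 16 gained and 10 of 82 lost regions in BE2C. Fisher's exact test, two-sided, gave p = 5.08e-06 in Kelly and 2.54e-10 in BE2C. The windows were chosen after the positions were seen, and neighbouring regions are not independent, so these p-values are too small. Genes in these windows were not analysed here.

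Longer peak lists with shAhR-2 may reflect technical differences between libraries or a response to this hairpin. When the pileups of shAhR-2 were thinned to the background of pLKO, keeping on average 0.595 of the depth in Kelly and 0.434 in BE2C, 52477 ± 3130 and 62233 ± 2522 peaks remained (SD, n = 3 each). These were 1.85 and 1.62 times the mean pLKO list, and the difference still passed the exact permutation test (p = 0.005), which argues against depth as the whole cause. The mitochondrial pileup over background of every other library was at least 1.59 times that of the highest shAhR-2 library of its line, so a larger share of mitochondrial reads in the shorter lists stays open. That comparison shows only that the ranges lie apart. How far such a share could shorten a list was not estimated. A response to shAhR-2 stays open too, since it was not separated from library preparation; shAhR-1, aimed at the same gene, gave no longer lists.

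The regions changed with shAhR-2 at matched length may partly follow from list length and signal over background, since the matched peaks are a smaller share of the longer lists. If so, the shAhR-1 library with the longest list in BE2C should have resembled shAhR-2 at these regions. It had the shAhR-2-gained regions more often than the other shAhR-1 libraries by 0.106 (share of regions) and the shAhR-2-lost regions more often, not less often, by 0.0799. The first value lies between the bounds set for the test and the second has the opposite sign, so list length and an effect of the hairpin cannot be told apart with 1 such library.

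The chromosome 2 block had a lower background relative to the genome with shAhR-2 than with pLKO, by log2 changes of −0.38 in Kelly and −0.58 in BE2C (exact permutation p = 0.01, adjusted p = 0.025 over 10 tests). Other bins of high background changed by −0.83 and −0.58, on average −0.70 (exact permutation p = 0.005, adjusted p = 0.0167), as a compression of high coverage in all such bins would give. Relative to those bins the block changed by 0.45 in Kelly, with a standard error of 0.13. This lay above the bound of −0.1 set for the test by more than that error. In BE2C the block changed by −0.00503 with a standard error of 0.19, which did not lie above that bound by more than its error. Over both lines the relative change did not pass the exact permutation test (p = 0.12, adjusted p = 0.2 over 10 tests). The other bins fell themselves, so values relative to them cannot decide on fewer copies, which stay open in both lines. What else could lower all high bins, such as a different share of mitochondrial reads, was not tested.

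Counts of changed regions were set against other splits of the same libraries. For both hairpins against pLKO at matched length, 3 of 84 choices of a control trio in Kelly and 2 of 84 in BE2C gave at least the real totals of 126 and 606, shares under 0.05. The median of the other choices was 14 in Kelly and 32 in BE2C. Libraries of a group shared more sequence than others, so a trio that is a real group can give a high total whatever the cause. The low shares therefore show that the pLKO libraries stood apart from the rest, and not why. With full lists the overlap of the hairpins in Kelly, 41 gained and 96 lost, was below the means of 42.7 and 165 from unchanged groups. The highest other totals, 420 and 917, came from setting apart the shAhR-2 trio, which points to a structure of the samples in which shAhR-2 stands alone. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In Kelly the real and highest other totals were 493 and 168 for shAhR-1, 961 and 83 for shAhR-2, and 1164 and 97 between the hairpins. In BE2C they were 1260 and 316, 2809 and 168, and 2115 and 189. For regions changed the same way in both lines, 1 of 200 arrangements for each hairpin gave as many (29 against 5 for shAhR-2, 11 against 3 for shAhR-1), but other arrangements call fewer regions per line. With lists of comparable length there were 2 arrangements for shAhR-2 and 3 for shAhR-1, too few for a share under 0.05. For both hairpins at matched length, 3 of the 68 comparable arrangements gave as many (3 against 7), a share under 0.05 that rests on 3 regions. Without replicate 1 of Kelly shAhR-1, 2 of 24 comparable arrangements gave at least 11, the highest with 46, and this share is not under 0.05. None of this separates the hairpin from library preparation, since the shAhR-2 libraries of both lines stood apart in list length, background and mitochondrial ratio. With full lists the count for both hairpins was 0, which leaves nothing to test. For shAhR-1 the full lists gave 14 regions, which 8 of 200 arrangements reached, the highest with 46. Among the 15 arrangements with comparable lists 8 reached it, and independent lists would share 7.04. For the 567 regions that differ between the lines, 1 of 100 splits, the real one, gave as many and the highest other gave 0. In the real split 2489 regions had an unadjusted p under 0.05. With a smallest p of 0.00025 over 16929 regions, splits that mix the lines could hardly pass the adjustment. The 0 therefore shows only that libraries of 1 line resemble each other.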
